A study of Mus musculus with 6 samples.

How the data were processed

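Whole ovaries of C57BL/6 mice aged 8 to 9 weeks were profiled by RNA sequencing in 2 groups of 3 libraries, control and cyclophosphamide (CTX). Per the labels' protocols, snap-frozen tissue was extracted with Trizol, 1 µg of total RNA went into an Illumina TruSeq RNA library, and sequencing ran on a HiSeq 2000. Dose, route, time after treatment and cycle stage are not given in the sources used here. No label says that the libraries of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.

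The authors deposited 1 table per library with a gene symbol, an Ensembl gene identifier and 1 value for each of 46078 genes. Bowtie 0.12.2 and the mm10 build are named in the submitters' processing notes. The read counter, annotation release, filters, strand use and treatment of reads with several matches are not given in the sources used here. The deposited values are taken as RPKM, which scale reads by gene length and by library depth, rounded to 2 decimals. No header states the unit, so it was read from the values. Among genes of at most 1000 exonic bases, values of at most 15 reads multiplied by exon length fell within 0.2 reads of a whole number in 97.6 to 98.0% of cases, with 1 step size per library. That step gives the depth: about 15900000, 15900000 and 16800000 reads in controls 1, 2 and 3, and 18100000, 22300000 and 17000000 in CTX 1, 2 and 3. Summed over genes with their exon lengths, the values imply 1.192 to 1.203 times as many assigned reads as this depth in each library, so the depth is the scale of the values and not a total of assigned reads. The cause of the excess was not tested. For a gene of 1 kilobase, an RPKM of 1 therefore stands for 15.9 to 22.3 reads. Exact read counts of longer genes are lost to rounding, so no counting interval is given, and count models were not used for the main results.

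Exon lengths, coordinates and gene types came from GENCODE M21 on GRCm38, the same assembly as mm10, and 45143 identifiers (98.0%) matched it. In the deposited symbols 27 names had turned into dates and 3 were blank, and all 30 were restored through their identifiers. Approximate reads were compared between libraries to look for a library deposited in duplicate. By mean chi-square per gene the closest pair was controls 1 and 2 (7.3, with 7.76 for CTX 2 and 3), where sampling noise alone gives about 1. By the median it was CTX 2 and 3 (1.31, with 1.53 for controls 1 and 2), where noise alone gives 0.45. Both pairs differ by more than noise on both measures, so all 6 libraries were kept as separate.

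The choices of test, filter, gene lists and naming rule were made before the data were examined, for counts and for normalized values alike, and the branch for normalized values applied. RPKM were transformed as log2(RPKM + 1), so fold changes of low genes are understated. Genes with an RPKM of at least 1 in at least 3 of the 6 libraries were kept, which left 14535. CTX was compared with control in limma 3.58.1 (R 4.3.3) with a linear model and moderated variances with a mean-variance trend. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. All adjusted p-values of single genes are from this limma test unless another is named, and tests are two-sided.

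For 29 gene lists, 15 on ovarian functions and treatment responses and 14 on cell types or RNA quality, limma's camera with a preset inter-gene correlation of 0.01 asked whether members ranked higher or lower than other genes. Lists with fewer than 5 tested members were not tested, which left 25 lists adjusted together. Of 664 list entries, 4 erythroid genes had no match in the tables. Camera was repeated with the correlation estimated per list, and limma's fry, which tests whether members move one way on balance without reference to other genes, was run on the same lists. Members were also adjusted over the list alone.

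The naming rule took the 6 largest changes per direction among called genes and up to 3 called members per list. If fewer than 5 genes passed, it took the 5 smallest p in each direction as not passing, the 2 most abundant members of each list on functions and responses, and the most abundant member of each cell type or quality list. The fallback applied here, and other genes are marked as chosen after their values were seen. Exceptions are Gm23935, given for its level, and genes given only because they overlap a named one. Exact permutation tests on list means of 3 against 3 libraries cannot give a p under 0.1.

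The alternatives were trimmed-mean scaling in the manner of TMM, quantile normalization, limma without trend, array weights, no filter, a mean RPKM of at least 5, pseudocounts of 0.1 and 0.5, a minimum log2 change of 1, the replicate number as a block, rescaling without the 20 most abundant genes, and each library left out in turn. Chosen after the data were seen were the first component of the residuals as a covariate, robust moderation, limma's voom on approximate reads, quantile normalization before the list tests, and other settings for library correlations. Each of the 10 splits of the 6 libraries into 3 and 3 was refitted.

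The limma and camera steps were tested on 5 simulated data sets with the real means and fitted variances of the 14535 genes. In each, 200 genes were changed by known amounts, drawn only from genes with a mean log2(RPKM + 1) above that of an RPKM of 5. The rates for lower genes were not simulated. Changes of a log2 of 1, 2, 3 and 4 were mixed in equal numbers in each set. Adjusted p under 0.05 recovered 62% of genes changed by a log2 of 1, 93.6% at 2, 98.4% at 3 and 98.8% at 4, and called 0.1% of unchanged genes. The larger changes ease the adjusted threshold for the smaller ones. The rates therefore do not give the power where few genes change or all changes are small. A list shifted by 0.75 was called in 5 of 5 sets and no unshifted list was called. The simulated genes varied independently, unlike the libraries themselves, where splits other than the labels called 4 to 13 lists. Tables were joined and figures drawn with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.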

Results

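RNA from whole mouse ovaries was sequenced in 3 control libraries and 3 libraries labelled CTX for cyclophosphamide, an alkylating chemotherapy drug that is toxic to the ovary. The values analysed were RPKM, scaled to an estimated depth of 15900000 to 16800000 reads in the control libraries and 17000000 to 22300000 in the CTX libraries. Between 13629 genes (CTX 1) and 14511 genes (control 3) reached an RPKM of 1. Gm23935, a short gene annotated as a microRNA on chromosome 16 (11144125 to 11144181), had the highest mean RPKM. It took 4.36, 3.88 and 4.40% of the summed RPKM in controls 1, 2 and 3 and 7.15, 1.49 and 3.92% in CTX 1, 2 and 3. Because RPKM divides by length, these are not shares of reads, which for so short a gene are far smaller.

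The series asks how cyclophosphamide affects the ovarian transcriptome. No single gene passed the test, and the closest were genes with lower levels in CTX. Slc27a6, a fatty acid transport protein gene, had 8.20 ± 0.499 RPKM in control and 3.43 ± 0.104 in CTX (mean ± SD, n = 3 each here and throughout). Ppl, encoding the plakin periplakin of desmosomes, had 6.03 ± 1.12 and 1.66 ± 0.0379. Coro2a, encoding an actin-binding coronin, had 9.63 ± 1.89 and 2.99 ± 0.601. Srd5a2, encoding a steroid 5-alpha-reductase, had 6.13 ± 0.743 and 1.99 ± 0.483. In each of these genes all CTX libraries lay below all control libraries, and control levels were 2.39 to 3.62 times those in CTX.

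The fitted log2 fold changes, CTX minus control, were −1.05 ± 0.11 (SE) for Slc27a6, −1.39 ± 0.16 for Ppl, −1.41 ± 0.18 for Coro2a and −1.26 ± 0.17 for Srd5a2. Their adjusted p-values in limma were 0.411, 0.411, 0.608 and 0.608. The fifth, Gm37261, an entry still to be experimentally verified, had 8.56 ± 2.03 and 2.01 ± 0.251 RPKM, a log2 fold change of −1.65 ± 0.18 and an adjusted p of 0.411. It lies in an intron of Mgst2, a microsomal glutathione S-transferase gene on the same strand, whose levels were 24.7, 24.95 and 20.8 in control and 23.6, 5.30 and 5.54 in CTX. Slc27a6 lies on chromosome 18 (58556257 to 58612773), Gm37261 on chromosome 3 (51672801 to 51673901), Ppl on chromosome 16 (5086291 to 5132421), Coro2a on chromosome 4 (46536937 to 46602202) and Srd5a2 on chromosome 17 (74016955 to 74047916), all in mm10 coordinates.

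Among genes with higher levels in CTX, the closest was 1110008P14Rik, a protein-coding gene on chromosome 2 (32377097 to 32381938), with 8.16 ± 0.226 RPKM in control and 13.5 ± 0.616 in CTX (log2 fold change 0.66 ± 0.10, limma adjusted p 0.959). It shares 728 of its 2694 exonic bases with Ciz1 on the opposite strand. Srm, encoding spermidine synthase on chromosome 4 (148591503 to 148594993), had 29.6 ± 2.94 and 44.8 ± 2.62 RPKM and the same adjusted p. The processed pseudogene Gm8451 had 3.30 ± 0.618 and 6.13 ± 0.265, and reads of its parent gene may be counted there. Snora57, a small nucleolar RNA, had 0.843 ± 0.742 and 4.42 ± 1.37, and Gm25948, annotated as a microRNA within Cep131, had 0.913 ± 0.307 and 2.63 ± 0.170. Gm25948 has 112 exonic bases and Snora57 148, so their values rest on far fewer reads than those of a gene of 1 kilobase. All CTX libraries lay above all control libraries in these 5 genes.

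Limma called 0 of 14535 genes higher and 0 lower, with a smallest adjusted p of 0.411. At an unadjusted p under 0.05 there were 501 genes (168 higher and 333 lower), where evenly spread p-values would give 727. That number does not allow for the division of controls 1 and 2 and CTX 1 from the rest, which widens the spread within groups. The groups did not overlap in 1283 genes (8.8%), where 10% would be expected if all 10 splits were alike. They were not alike, since controls 1 and 2 and CTX 1 against the rest separated 47.5% of genes. The 8 remaining splits separated 2.5 to 8.1% and had 61 to 326 genes at an unadjusted p under 0.05. With the labels these are 9 splits, which cannot give a share under 0.11. Limma's voom on approximate reads also called 0 genes, with 470 at an unadjusted p under 0.05. With array weights 4062 genes were higher and 2747 lower, but the weights were 0.25 for control 3 and 0.08 for CTX 1 against 1.06 to 6.36 for the other libraries. Without CTX 1 there were 5 calls (Slc38a3 and C7 higher, Hao2, Pgbd5 and Mgst2 lower, named after their values were seen). CTX 1 did not share the rise of Slc38a3 (6.06 RPKM against 6.49 to 9.18 in control and 40.4 and 38.1 in CTX 2 and 3). Nor did it share that of C7 (0.77 against 1.23 to 1.85, and 9.72 and 9.74). Its Mgst2 value (23.6) lay within the controls, and its Hao2 and Pgbd5 values lay between the controls and CTX 2 and 3. With the first residual component as a covariate, chosen after the data were seen, 73 genes were higher and 86 lower.

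**Figure D1:**
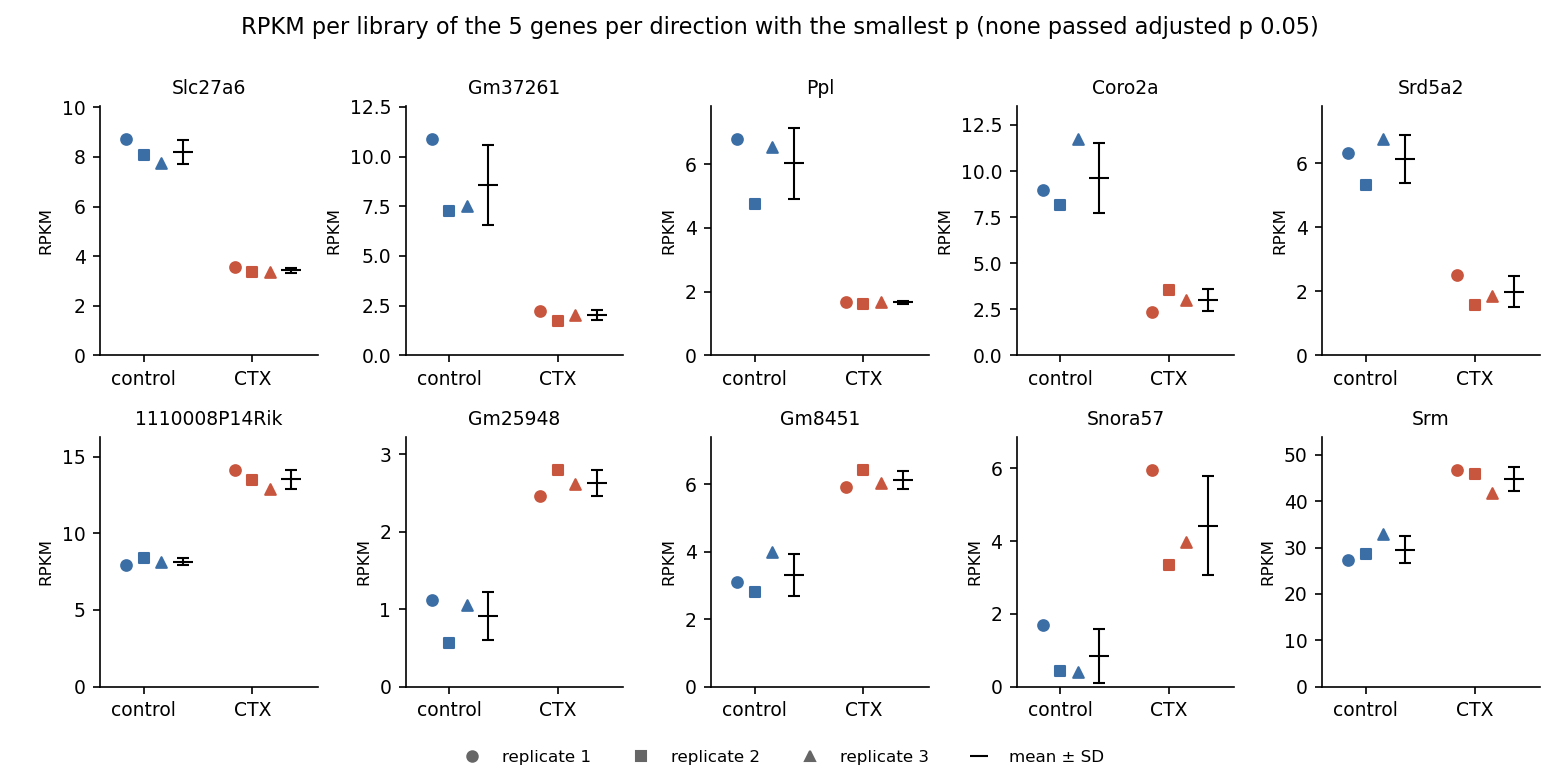
RPKM (y axis, from 0) of the 5 genes with the smallest p in each direction, by group (x axis), with a point per library, shaped by replicate number, and a bar for the mean ± SD of 3 libraries. In each of the 10 genes the control and CTX points do not overlap, for example 7.76 to 8.74 against 3.36 to 3.55 in Slc27a6, and none passed the adjusted threshold.

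Genes of the ovarian surface epithelium and mesothelium, the cell layer that covers the ovary, ranked lower in CTX than other genes. Camera gave an adjusted p of 9.81e-07, but the adjusted p = 0.745 with an estimated correlation and 0.839 with fry. Of 13 tested members 12 had negative log2 fold changes, with a median of −0.42 (quartiles −0.57 to −0.33), and in 6 of them all CTX libraries lay below all controls. The members Upk1b, Msln, Muc16 and Epcam were chosen after their values were seen. The uroplakin gene Upk1b had 11.8 ± 0.562 RPKM in control and 7.66 ± 1.23 in CTX, and the mesothelin gene Msln 10.04 ± 1.73 and 7.06 ± 0.290. The mucin gene Muc16 had 3.14 ± 0.554 and 1.65 ± 0.220, and the adhesion gene Epcam 7.53 ± 2.09 and 4.07 ± 1.18. The keratin gene Krt8, the most abundant member and the one named by the rule, went the other way with 16.3 ± 3.01 and 19.2 ± 2.12. No member passed over all genes and 2 (Upk1b and Muc16) passed as lower when adjusted over the list alone.

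Of 25 lists tested, camera with the preset correlation ranked 4 lower and 6 higher in CTX. None passed with an estimated correlation (smallest adjusted p = 0.745) or with fry (smallest adjusted p = 0.839). Over the 29 lists, 0 members passed over all genes in either direction, and adjusted over the list alone 0 were higher and 2 lower, the pair in the surface epithelium list. The surface epithelium and erythroid lists passed with each library left out in turn (highest adjusted p = 0.00315 and 0.0111). The other 8 lists lost their call without at least 1 library. The ribosomal list lost it without CTX 1 (adjusted p = 0.605), and oxidative phosphorylation without control 3 (0.576) or, by turning, CTX 1. The oocyte, luteal and proliferation lists lost it without control 1, control 2, CTX 2 or CTX 3 (up to 0.503, 0.736 and 0.853). The macrophage list lost it without control 1, CTX 2 or CTX 3 (up to 0.812), and the endothelial and adipocyte lists without control 2, CTX 2 or CTX 3 (up to 0.369 and 0.0893).

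Follicle genes differed more between libraries of the same group than between the groups. Oocyte genes had a mean log2(RPKM + 1) of 3.07, 2.92 and 3.88 in controls 1, 2 and 3 and 2.66, 3.98 and 4.01 in CTX 1, 2 and 3. Gdf9, the oocyte growth factor, had 37.4 ± 16.7 RPKM in control and 49.6 ± 27.7 in CTX, and Padi6, an oocyte cytoplasmic lattice gene, had 41.4 ± 21.2 and 58.8 ± 34.0. The list ranked higher in CTX by camera (28 of 31 members positive, adjusted p = 0.0114, adjusted p = 0.879 with an estimated correlation). Granulosa cell genes showed the same division of the libraries, with 15 of 26 members positive and a camera adjusted p of 0.538. Inha, encoding the inhibin alpha subunit, had 1097 ± 770 and 1239 ± 696, and the gap junction gene Gja1 had 562.5 ± 154 and 636.6 ± 288.

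Luteal cell genes showed the opposite, with list means of 7.37, 7.58 and 5.72 in controls 1, 2 and 3 and 7.69, 5.66 and 5.67 in CTX 1, 2 and 3. All 17 tested members had negative fitted fold changes (median −0.33), and camera ranked the list lower (adjusted p = 0.0412, adjusted p = 0.879 with an estimated correlation). Hsd3b1, a steroid dehydrogenase gene of progesterone synthesis, had 3912 ± 897 RPKM in control and 3107 ± 1984 in CTX, and Cyp11a1, which starts steroid synthesis from cholesterol, had 1626 ± 737.5 and 1471 ± 1152. Cholesterol synthesis genes divided the libraries as luteal genes did (20 of 25 members negative, camera adjusted p = 0.538). Hsd17b7 had 174, 270.4 and 11.5 RPKM in controls 1, 2 and 3 and 176, 9.58 and 10.3 in CTX 1, 2 and 3, and Hmgcs1 had 246.6 ± 144 and 249.9 ± 309. Ovulation genes had 3 of 8 members positive (camera adjusted p = 0.875), with 78.8 ± 28.1 and 77.2 ± 75.7 for Rgcc and 37.5 ± 17.7 and 41.3 ± 55.0 for Cited4. Theca and interstitial genes had 10 of 16 members positive (camera adjusted p = 0.0828), and Aldh1a1 had 972 ± 215 and 1117 ± 411.

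**Figure D2:**
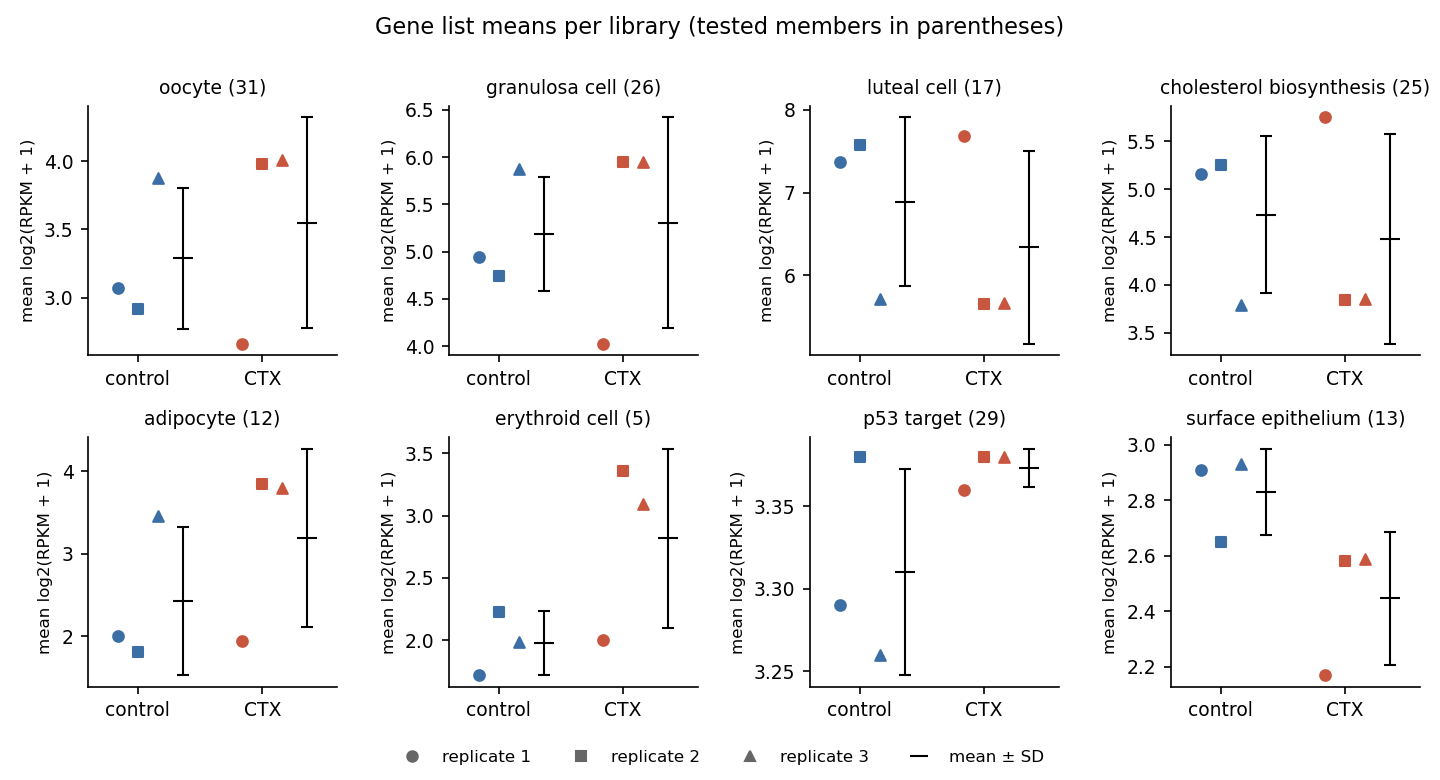
Mean log2(RPKM + 1) of the tested members of 8 gene lists (y axis, not starting at 0) by group (x axis), with a point per library, shaped by replicate number, and a bar for the mean ± SD of 3 libraries. Control 3 sits with CTX 2 and 3 in the oocyte, granulosa, luteal, cholesterol and adipocyte panels, while all CTX points of the surface epithelium panel (2.17 to 2.59) lie below all control points (2.65 to 2.93).

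Lists of responses to DNA damage did not pass. For p53 targets, genes switched on after DNA damage, the median log2 fold change was 0.04 over 29 members (camera adjusted p = 0.541). The cell death gene Bax, which is also on the apoptosis list, had 54.2 ± 5.70 RPKM in control and 67.1 ± 31.2 in CTX, and Ei24 had 45.6 ± 2.51 and 42.0 ± 1.76. DNA repair genes had a median of 0.06 over 34 members (camera adjusted p = 0.176), with 39.4 ± 11.3 and 47.8 ± 6.03 for the histone gene H2afx and 35.98 ± 7.33 and 40.7 ± 11.4 for Parp1. Apoptosis genes had 10 of 26 members positive (camera adjusted p = 0.809), with a median of −0.01 where the mean and the test pointed up, and Mcl1 had 76.1 ± 12.0 and 68.4 ± 13.0.

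Proliferation genes ranked higher in CTX by camera with a median of 0.12 (31 of 34 members positive, adjusted p = 0.0412, adjusted p = 0.879 with an estimated correlation), and the call was lost without a filter on low values (adjusted p = 0.0648) and the direction turned without control 1. The list means were 3.10, 3.28 and 3.98 in controls 1, 2 and 3 and 3.04, 3.86 and 3.86 in CTX 1, 2 and 3, so the libraries divided as for oocyte genes. The replication genes Pcna and Mcm7 had 46.8 ± 6.73 and 49.4 ± 3.42 RPKM, and 23.6 ± 8.84 and 26.1 ± 7.08, in control and CTX. Oxidative phosphorylation genes had a median of 0.11 (29 of 36 positive, camera adjusted p = 0.0412, adjusted p = 0.879 with an estimated correlation), and the call was lost without a filter (adjusted p = 0.0648) and after quantile normalization (adjusted p = 0.538), and the list ranked lower without CTX 1, whose list mean of 6.95 stood above the 6.20 to 6.44 of the other libraries. Among its members, Cox6a1 had 338 ± 59.6 and 399.5 ± 219, and Cox8a 321 ± 30.7 and 316 ± 133.

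Extracellular matrix genes had 17 of 34 members positive (camera adjusted p = 0.766), with 461 ± 149.5 and 428 ± 220.5 RPKM for Sparc and 276 ± 82.4 and 404 ± 56.4 for the smooth muscle actin gene Acta2. Detoxification genes had 20 of 32 members positive (camera adjusted p = 0.548), and the glutathione peroxidase gene Gpx3 had 491 ± 118 and 372 ± 121. In the list of follicle activation through PI3K, AKT and mTOR 10 of 24 members were positive (camera adjusted p = 0.624), with 121 ± 22.9 and 83.8 ± 52.2 for the cell cycle inhibitor Cdkn1b and 63.8 ± 2.42 and 67.4 ± 3.42 for Akt1. Interferon response genes had 13 of 27 members positive (camera adjusted p = 0.652) and a median of −0.01, again with an upward mean and test. Values were 322 ± 45.8 and 341 ± 216 for Bst2 and 40.5 ± 18.7 and 47.6 ± 4.18 for Ifi27l2a.

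Endothelial and macrophage genes ranked lower in CTX. Endothelial genes had 14 of 16 members negative with a median of −0.17 (camera adjusted p = 0.00882, adjusted p = 0.745 with an estimated correlation). Their list means were 3.58, 3.63 and 3.56 in controls 1, 2 and 3 and 3.54, 3.42 and 3.37 in CTX 1, 2 and 3. All CTX means lay below all control means, as in the surface epithelium list, and each of these lists had an exact permutation p of 0.1, the smallest possible. The tight junction gene Cldn5 had 36.7 ± 5.50 and 32.9 ± 5.70 RPKM. Macrophage genes had 14 of 17 members negative with a median of −0.12 (camera adjusted p = 0.0412, adjusted p = 0.879 with an estimated correlation), and the lysozyme gene Lyz2 had 241 ± 71.0 and 220.1 ± 53.5. Erythroid genes ranked higher with a median of 1.01 over 5 members (camera adjusted p = 0.000654, adjusted p = 0.745 with an estimated correlation). The hemoglobin gene Hbb-bs had 10.7, 13.8 and 12.1 RPKM in controls 1, 2 and 3 and 12.1, 39.99 and 35.1 in CTX 1, 2 and 3.

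Adipocyte genes ranked higher in CTX with a median of 1.13 (10 of 12 members positive, camera adjusted p = 0.0127, adjusted p = 0.745 with an estimated correlation), but again by library. The adipsin gene Cfd, chosen after its values were seen, had 1.63, 0.07 and 90.8 RPKM in controls 1, 2 and 3 and 0.48, 109 and 97.1 in CTX 1, 2 and 3. Plin4, the most abundant member, went the other way with 157, 216 and 18.0 in control and 190, 10.9 and 9.90 in CTX. Ribosomal protein genes ranked higher with a median of 0.19 (29 of 31 positive, camera adjusted p = 6.08e-06, adjusted p = 0.879 with an estimated correlation), and Rplp1 had 1213 ± 99.9 and 1688 ± 437. The list means were 7.25, 7.23 and 7.54 in controls 1, 2 and 3 and 7.80, 7.37 and 7.43 in CTX 1, 2 and 3, so control 3 lay above CTX 2 and 3 and the rank rested on CTX 1. CTX 1 was also the only library whose deviations from the mean of all 6 fell with exon length (Spearman correlation −0.27 against 0.01 to 0.15).

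The other composition lists did not pass by camera. Smooth muscle and pericyte genes had an adjusted p of 0.0598 and a median of 0.33 (9 of 14 positive), oviduct epithelium 0.323 and 0.15 (Tppp3 5.86 ± 2.84 and 10.8 ± 6.29 RPKM), immediate early genes of tissue handling 0.153 and −0.10 (Jund 54.6 ± 2.74 and 53.4 ± 21.6), and mitochondrially encoded genes 0.548 and −0.13 (mt-Co1 8095 ± 653 and 7147 ± 1614). The lymphocyte, neutrophil, skeletal muscle and replication-dependent histone lists had only 4, 2, 3 and 4 members above the filter and were not tested. Their most abundant members were Igkc with 9.37 ± 1.82 and 5.57 ± 4.41, Ltf with 2.90 ± 2.05 and 2.06 ± 2.77, Mylpf with 2 ± 0.211 and 2.34 ± 1.34, and Hist1h2bc with 46.5 ± 18.5 and 49.8 ± 35.9.

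Libraries of the same group were not more alike than libraries of different groups. The mean Pearson correlation across genes was 0.949 within groups and 0.952 between them, where genes are not independent replicates. The closest pairs were CTX 2 and CTX 3 (0.990), controls 1 and 2 (0.987), control 3 and CTX 3 (0.981) and control 3 and CTX 2 (0.978), and the most distant were CTX 1 and CTX 3 (0.908). The first principal component held 68.3% of the variance and placed controls 1 and 2 and CTX 1 on one side and control 3 and CTX 2 and 3 on the other. The second held 15.4%, with controls between 0.1 and 21.5 and CTX libraries between −25.8 and −4.2. No label records a batch, so no value within batches can be given.

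**Figure D3:**
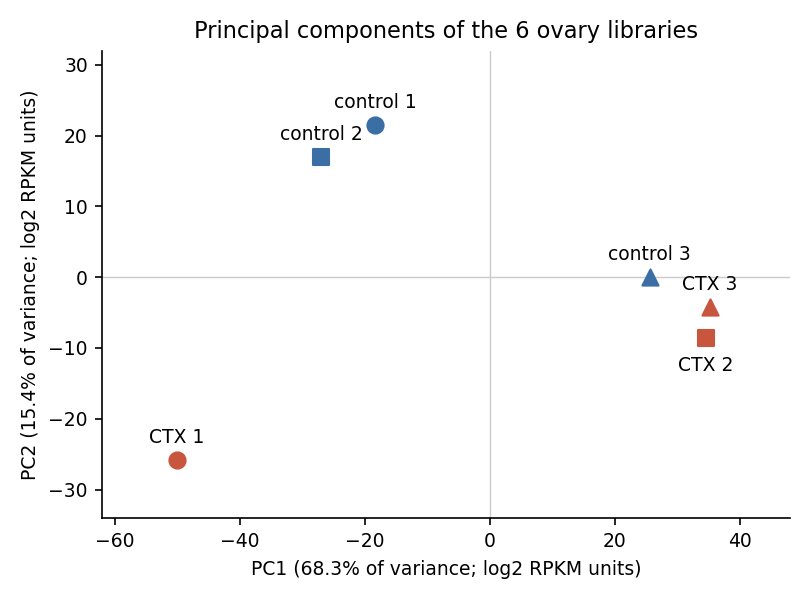
First and second principal components of log2(RPKM + 1) over 14535 genes, with the share of variance on each axis, blue points for control and red for CTX, shaped by replicate number. On the first component control 3 (25.6) lies beside CTX 2 (34.6) and CTX 3 (35.2), and CTX 1 (−50.1) lies on the side of controls 1 and 2 (−18.3 and −27.0).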

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

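Robust moderation, voom, the residual covariate, quantile normalization before the list tests and the settings for library correlations were chosen after the data were seen and the rest before; alternatives planned for count tables did not apply. Under 11 other scalings, filters, pseudocounts and tests no gene passed (smallest adjusted p from 0.272 to 1, 309 to 990 genes at an unadjusted p under 0.05), nor with a minimum log2 change of 1. Array weights gave 4062 higher and 2747 lower genes, with control 3 and CTX 1 weighted least, and the residual covariate gave 73 and 86. Leaving out 1 library gave 0 to 2 higher and 0 to 3 lower genes, all 5 without CTX 1 (adjusted p 0.0487). The lists called numbered 10, and 4 to 15 with 1 library left out, and 0 with an estimated correlation or with fry. Without a filter 29 lists were tested and 9 called. Of the 10, 8 were kept (proliferation and oxidative phosphorylation lost, adjusted p = 0.0648 each). After quantile normalization 10 were called and 9 of the 10 kept (oxidative phosphorylation lost, adjusted p = 0.538). A list outside the 10 was thus gained in each of these settings. The replicate block gave 0 higher and 0 lower genes and 11 lists. Deviations of same-numbered samples correlated at 0.40, −0.54 and 0.60 for numbers 1, 2 and 3. Controls 1 and 3 correlated best with the CTX library of their own number, and control 2 with CTX 1. In the division across the labels, libraries numbered 1 share a side, as do those numbered 3, while those numbered 2 do not. These correlations follow that division and cannot decide whether the numbers pair the samples. The difference in correlation within and between groups was −0.0032, and −0.0056 to −0.0031 under other settings.

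Of the 50 named genes, none of them called in the main fit, array weights called 40 and the residual covariate 9 (Slc27a6 at adjusted p = 0.00131 and 0.0202). Of the 50, 19 turned direction when 1 library was left out. Their log2 fold changes ranged from −0.18 to 0.54 for Gja1, −0.13 to 0.43 for Bax, −0.29 to 0.34 for Cox6a1, −0.22 to 0.39 for Mylpf, −0.18 to 0.80 for Inha, −0.03 to 0.43 for Mcm7, −0.32 to 0.10 for Lyz2, −0.58 to 0.25 for Hist1h2bc, −0.56 to 0.05 for Sparc, −0.05 to 0.88 for Gdf9, −0.88 to 0.02 for Cyp11a1, −0.04 to 0.50 for Aldh1a1, −1.14 to 0.03 for Rgcc, −1.53 to 0.04 for Hmgcs1, 0.00 to 0.40 for Parp1, −0.57 to 0.18 for Bst2, −0.42 to 0.07 for Cox8a, −0.41 to 0.09 for Jund and −1.73 to 0.01 for Cited4. Adjusted p of the lists that turned ranged from 8.07e-07 to 0.853 for proliferation and 6.67e-07 to 0.576 for oxidative phosphorylation. Quantile normalization turned Gja1 (−0.01), Akt1 (0.00) and mt-Co1 (0.13), and array weights turned Bax (−0.18), Cox6a1 (−0.30) and Mylpf (−0.24). Bax, Cox6a1 and Mylpf also turned without CTX 1 (−0.13, −0.29 and −0.22), the library with the smallest array weight (0.08), so their turns rested on CTX 1. The cause of the other turns was not tested. Depth limits genes near an RPKM of 1, where 15.9 to 22.3 reads stand behind a gene of 1 kilobase.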

Other observations

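The genes named here and the tests of explanations were chosen after the results were seen, except the fits without 1 library, which were planned. The 4 genes H2-Aa, H2-Ab1, H2-Eb1 and Cd74 of MHC class II antigen presentation, picked for their separation, had lower values in CTX, and none passed. H2-Aa had 56.1 ± 4.89 RPKM in control and 34.3 ± 2.95 in CTX, H2-Ab1 46.6 ± 5.80 and 28.7 ± 3.89, H2-Eb1 68.4 ± 8.43 and 41.15 ± 3, and Cd74, their invariant chain, 134.7 ± 10.1 and 86.9 ± 11.4 (n = 3 each). Their log2 fold changes were −0.71 to −0.63, and none passed over all genes (limma adjusted p of 0.959 or more). Other genes with separated groups were Aldh1a2, a retinoic acid synthesis gene, with 40.9 ± 7.85 and 21.7 ± 4.31, the aldehyde oxidase genes Aox1 with 9.01 ± 1.52 and 4.39 ± 0.702 and Aox3 with 2.78 ± 0.707 and 0.977 ± 0.137, and Insl3, a hormone gene of theca cells, with 9.95 ± 2.96 and 17.6 ± 0.596.

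The steroid enzyme genes Cyp17a1 of theca cells and Cyp19a1 of granulosa cells were highest in CTX 2 and 3, given here as values without a test of that division. Cyp17a1 had 20.2, 6.78 and 59.9 RPKM in controls 1, 2 and 3 and 24.1, 239 and 224 in CTX 1, 2 and 3. Cyp19a1, encoding aromatase, had 5.77, 3.96 and 8.51 and then 0.53, 32.8 and 33.9, while Star, the cholesterol carrier, had 543, 532 and 293 and then 572, 65.8 and 65.0. Among p53 targets Cdkn1a had 11.5, 18.2 and 3.99 in control and 20.9, 7.51 and 6.74 in CTX.

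Lower levels of these 4 MHC class II genes may reflect fewer macrophages, one of the cell types that carry them. The macrophage list had a median log2 fold change of −0.12 (quartiles −0.23 to −0.02), above the highest value of the 4 genes at −0.63. The list was fixed beforehand and the 4 genes were not, so this comparison cannot decide on a loss of macrophages. Dendritic cells had no list, B cells only a share of the lymphocyte list that had too few tested members, and a lower level per cell was not tested. The 4 genes were picked for their separation by the labels, which no other split can then show, so the 10 splits cannot weigh it.

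The libraries part across the labels, as controls 1 and 2 and CTX 1 against control 3 and CTX 2 and 3, which points to a structure of the samples. This split called the most genes of all 10 (3478, with 47.5% of genes separated). The count describes the same division as the first principal component and is no separate evidence for it. Attached fat diluting the ovarian RNA would lower oocyte and luteal genes together, but in control 3 against controls 1 and 2 the median log2 difference was 0.94 for oocyte genes and −1.52 for luteal genes, which argues against fat as the whole cause. Fat may still account for a part, since adipocyte genes had a median difference of 1.58 there (quartiles 0.30 to 2.84) and of −2.39 in CTX 1 against CTX 2 and 3 (quartiles −3.36 to −0.46), although Plin4 went the other way. If an exon length trend were the cause, a correction on length would end the calls. With the correction 3698 of 14477 genes were called, against 3478 of 14535 without it. Only these counts were compared, and CTX 1 alone had a negative length correlation (−0.27 against 0.01 to 0.15). An exchange of the labels of control 3 and CTX 1 could place the libraries this way. The deposited labels separated 134 genes by at least 0.25 on the log2 scale against at most 59 in the 8 other splits that break the large one. The gap was chosen after the data were seen, and the lead was smaller with a gap of 0.5 (26 genes against at most 18) or none (1283 against at most 1183). The smallest share 9 splits can give is 0.11, so an exchange and a difference in cycle stage between animals, which the labels do not give, stay open and cannot be told apart here.

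The surface epithelium list could rank lower because of CTX 1 alone, where its mean was lowest (2.17). Without CTX 1 it still ranked lower, with an adjusted camera p of 0.00315 (1.82e-09 to 0.00315 over the 6 libraries left out), which argues against that library as the whole cause of the call at the preset correlation. With all libraries the list did not pass with an estimated correlation (adjusted p = 0.745) or with fry (adjusted p = 0.839). Of the 10 splits, 1 (the real one) had as small a p, 3.92e-08 against 3.43e-05 for the smallest of the others, and 10 splits are too few for a share under 0.05. The split that an exchange of control 3 and CTX 1 would give had a camera p of 0.826 with the list upward, so the lower rank depends on the deposited labels of these 2 libraries. The amount of surface kept at dissection was not tested and stays open beside the treatment.

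For the counts, 10 splits are likewise too few for a share under 0.05. Every split has at least the 0 calls of the labels, so genes at an unadjusted p under 0.05 were compared instead. As many (501) were found in 2 of the 10 splits, the labels themselves and the division across them (5573). The 8 remaining splits had at most 326. As many lists (10) were called in 4, with 13 as the highest other. With the residual covariate, as many genes (159) were called in 3, with 6378 as the highest other.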
